A study of Rattus norvegicus with 48 samples.

How the data were processed

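Sperm DNA of rats was profiled by methylated DNA immunoprecipitation sequencing (MeDIP-seq), in which fragments that carry methylated cytosine are enriched with an antibody before sequencing. The series holds 8 groups of 6 libraries, 48 in all: control F1, F2 and F3, and exposed F1, F2, F3, F4 and F5. Each library is a DNA pool; per the labels' protocols a pool holds sperm DNA of 10 to 11 animals in equal amounts, except that 1 control pool holds 5, and the labels do not say which one. The groups come from the generation and lineage labels, and the pool numbers within a group only name the pools.

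The authors deposited 5 tables, each for an exposed generation, with a grid of 1000 bp windows over chromosomes 1 to 20, X, Y and the mitochondrial genome. Per the file headers, each library has a column of read counts taken from its alignment, and the values are whole numbers that were not normalised. The submitters' processing notes name FastQC, Trimmomatic, Bowtie2, SAMtools and edgeR without versions, and the rat build Rnor_6.0; filters on reads are not given in the sources used here. The tables also hold the authors' deposited log2 fold changes and p-values from edgeR. From the values, these log2 fold changes are control over exposed, opposite in sign to every fold change below, and the authors' p-values cover the windows whose 12 counts sum to 120 or more. The control F3 columns are identical in the F3, F4 and F5 tables. No column lacked a sample, and no input library was used here, so a window's count reflects its methylation together with its copy number, sequence content and mappability.

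Counts were analysed with edgeR 4.0.16, limma 3.58.1 and R 4.3.3. Each comparison used the 12 libraries of its 2 groups, windows on chromosomes 1 to 20, X and Y with a mean of at least 5 reads per library, TMM scaling and edgeR's quasi-likelihood test, two-sided. A window was called at a Benjamini-Hochberg adjusted p under 0.05, and called windows of the same direction within 1000 bp were merged into regions. Fold changes are exposed over control, or the later over the earlier generation, as log2 values with their standard error (SE); levels are CPM, a window's reads as a share of all reads of its library. The exposed generations were compared with the control group of the same generation; exposed F4 and F5 were compared with control F3, where the control lineage ended. Generations of the control lineage, and exposed F3, F4 and F5, were compared in the same way, and differences of effects between generations were tested as interaction contrasts over the 36 pools of F1 to F3. Shares of reads per pool were compared with exact two-sided permutation tests over the 12 pools, adjusted over a family of 15 tests. The places of called windows were compared with those of all tested windows by Fisher's exact test, as a description, since neighbouring windows are not independent. P-values of tests between groups of pools weigh a difference against the spread between pools of a group, while Fisher's exact test counts windows. In edgeR's quasi-likelihood test the spread of each window is drawn toward that of all windows. Its p-values and SEs can therefore be small where the pools of that window vary widely.

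Named windows were chosen by a rule fixed before the data were examined: per main comparison, the 5 called windows with the smallest p in each direction; in a direction with fewer than 4 called windows, the 3 with the smallest p there, said where they do not pass the test; and up to 5 windows called in the same direction in F3, F4 and F5 or in F1, F2 and F3. The design also planned promoter counts, gene lists, CpG density classes and markers of somatic cells. These need a gene annotation and genome sequence of the build of the tables; none was used here, so windows are named by coordinates of Rnor_6.0 and no gene is assigned to them. The share of reads in the 1 percent of windows with the most reads took the place of the CpG-based measure of enrichment.

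Libraries held 9.98 to 34.9 M counted reads. The test was tried on simulated counts drawn from each comparison's means, dispersions and library sizes, with 200 windows changed. It recovered 65.2 to 77.3 percent of the windows changed 4-fold over the 5 main comparisons, 13.4 to 23.9 percent of those changed 2-fold and at most 1.49 percent of those changed 1.5-fold. False calls numbered 6, 10, 3, 8 and 5 in F1 to F5. Beside them stood 47, 51, 43, 44 and 47 recovered windows of the 4-fold changes and 16, 13, 9, 14 and 9 of the 2-fold changes. In the data F3 and F4 called 3 and 9 windows, although the number truly changed there is not known. No 2 pools of a group agreed within sampling noise: over the 120 pairs of pools within groups the chi-square per degree of freedom lay between 1.42 and 4.02, so all 48 were counted as separate samples.

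Alternatives set in advance were DESeq2 size factors inside edgeR, scaling by total count, no filter or a mean of at least 20 reads, limma-trend on log2 CPM with a prior count of 2, edgeR's exact test, an adjusted p under 0.01, an unadjusted p under 1e-06, all 8 groups in 1 fit, and leaving out each pool in turn. Alternatives chosen after seeing the data were TMM factors within 10 classes of mean read count, 2 surrogate variables as covariates, other control groups, and leaving out the pool of each group that correlated least with the others. For F3, F4 and F5, which share control F3, overlaps and correlations were set beside simulated unchanged groups and repeated with the 6 control pools divided 3 and 3. Splits of the pools into other groups were drawn at random, 40 for each comparison of 2 groups and 32 for each interaction, on windows with a mean of at least 15 reads.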

Results

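Sperm was collected at 1 year of age from outbred Hsd:Sprague Dawley rats of a control and an exposed lineage. In the exposed lineage, pregnant F0 females were injected with vinclozolin, a fungicide that blocks androgen action, at 100 mg/kg. Pregnant F1 females then received JP8, a kerosene-based jet fuel, at 250 mg/kg, and pregnant F2 females DDT, an organochlorine insecticide, at 25 mg/kg, each on embryonic days 8 to 14. F3 and F4 pregnancies were untreated, so that the F5 animals were the first without direct exposure of themselves or their precursor germ cells to any of the compounds. Control F0 females received the solvent DMSO, and their lineage was bred to F3. MeDIP-seq read counts were compared over 8 groups of 6 pools: control F1, F2 and F3 and exposed F1, F2, F3, F4 and F5.

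The 48 libraries held 9.98 to 34.9 M counted reads, with a median of 21.8 M. Group medians ran from 19.6 M in exposed F1 to 28.1 M in control F1, so the F1 comparison had the widest gap in depth between its groups. Reads at the windows named below ran from 5 in the 6 control F3 pools and 55 in the 6 exposed F4 pools, at chromosome 8 113764001 to 113765000, to 1439 and 942 in the same groups at chromosome 7 123397001 to 123398000.

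The first comparison asked which sperm regions differed in F1 males, whose mothers were treated with vinclozolin while carrying them. Exposed F1 sperm carried more MeDIP reads than control F1 sperm in 1613 windows and fewer in 605, out of 1384497 tested. The balance of the 2 directions moved with the method: 3622 and 832 with TMM within classes of read count, 2250 and 1710 with edgeR's exact test, and 3129 and 2722 with 2 surrogate variables. The window at chromosome 3 118675001 to 118676000 rose 5.58-fold, from 0.344 ± 0.0690 to 1.78 ± 1.26 CPM (SD, n = 6; log2 fold change 2.48 ± 0.27, SE; edgeR adjusted p = 6.12e-10), and lay above every control pool in 5 of 6 exposed pools. Windows at chromosome 8 3368001 to 3369000, chromosome 14 54147001 to 54148000, chromosome 16 53012001 to 53013000 and chromosome 18 88082001 to 88083000 rose 3.26-, 2.57-, 3.38- and 2.74-fold (log2 SE 0.18 to 0.24; largest edgeR adjusted p = 4.47e-06). In the same order, 3, 5, 6 and 6 of 6 exposed pools lay above every control pool. The pools at chromosome 8 3368001 varied widely, with 0.983 ± 0.304 CPM in control F1 and 2.78 ± 2.15 in exposed F1 (SD, n = 6). The window on chromosome 18 belonged to a region of 4 called windows between 88079001 and 88084000, with a mean log2 fold change of 1.46. Regions of 3 called windows rose at chromosome 14 101991001 to 101994000 (mean log2 fold change 1.53) and chromosome X 73399001 to 73402000 (0.84). Of the 2153 called regions, 2092 were single windows.

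Among the windows that fell in exposed F1, the one at chromosome 1 262234001 to 262235000 went from 2.21 ± 0.212 to 0.983 ± 0.189 CPM (SD, n = 6), 0.452-fold, with all 6 exposed pools below every control pool (log2 fold change −1.14 ± 0.18, SE; edgeR adjusted p = 0.000262). Chromosome 20 32339001 to 32340000 (0.522-fold) and chromosome 10 47162001 to 47163000 (0.372-fold) also separated all 6 exposed from all 6 control pools. At chromosome 13 30579001 to 30580000 (0.447-fold) and chromosome 2 29456001 to 29457000 (0.232-fold), 5 of 6 exposed pools lay below every control pool. The 1384497 tested windows were also ranked by read count into 8 equal classes. The class with the most reads held 1217 of the 1613 windows that rose and 269 of the 605 that fell. At chromosome 3 118675001 control F3 measured 1.54 ± 1.31 CPM and control F2 0.503 ± 0.203 (SD, n = 6). Against control F3 instead of control F1, edgeR called 0 windows in exposed F1 (58922 at an unadjusted p under 0.05), and against control F2 it called 99. Limma-trend called 113 in the comparison with control F1 and ended the calls named on chromosomes 8, 14 and 18 (adjusted p 0.0548 to 0.0934). Without single pools the F1 count ran from 598 (without control F1 replicate 2) to 3765 (without exposed F1 replicate 2).

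**Figure D1:**
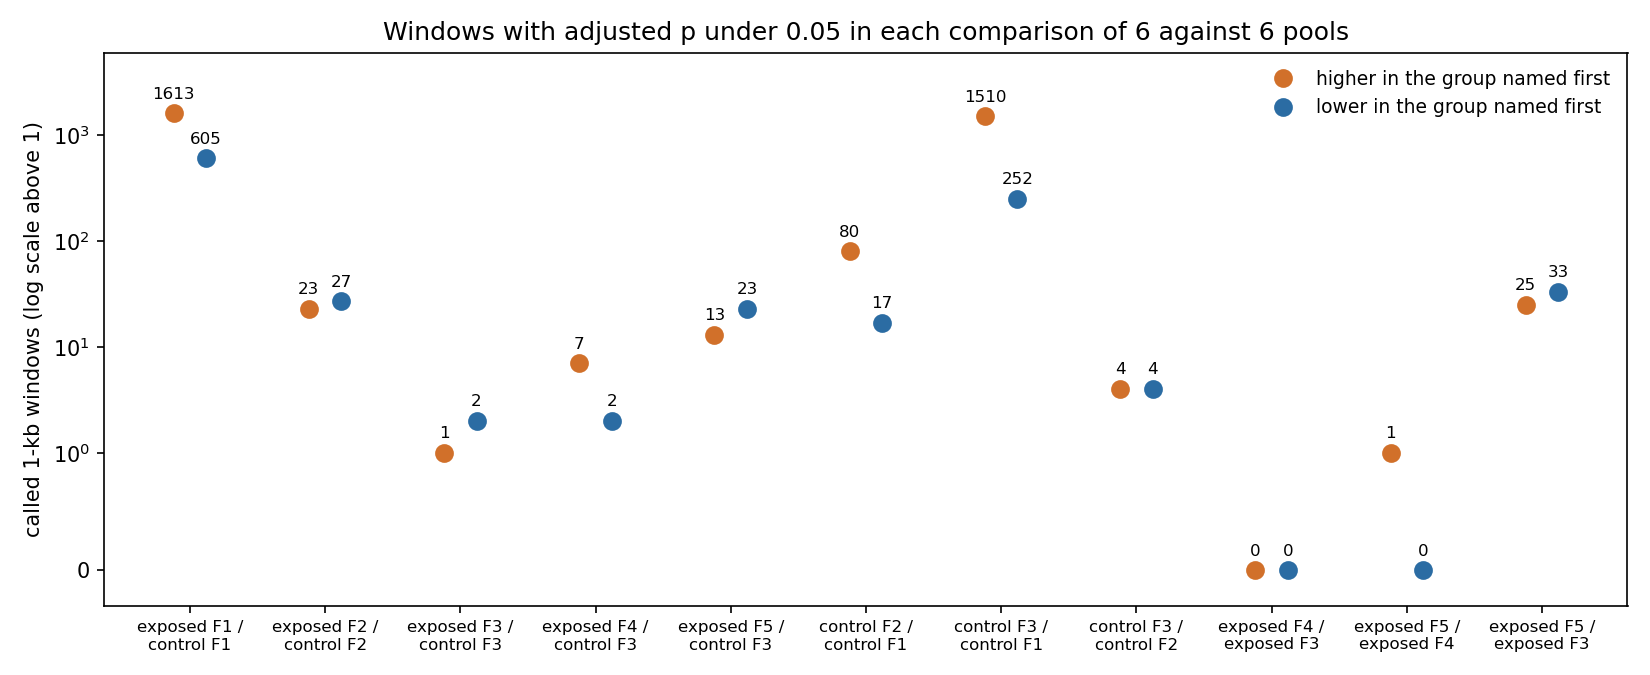
Number of called windows (log scale above 1) in each main comparison, in the control lineage between generations and in the exposed lineage between generations, higher and lower calls apart. F1 (1613 higher, 605 lower) and control F3 against control F1 (1510 higher, 252 lower) stand above the others, which hold at most 97 calls.

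F2 males descended from a grandmother given vinclozolin and were carried by a mother given JP8. Exposed F2 sperm carried more reads than control F2 sperm in 23 windows and fewer in 27, each a separate region, of 1256523 tested. At chromosome X 136411001 to 136412000 reads rose 3.11-fold, from 0.641 ± 0.137 to 2.18 ± 1.15 CPM (SD, n = 6; log2 fold change 1.64 ± 0.26, SE; edgeR adjusted p = 0.00344). Windows at chromosome 16 64947001 to 64948000 (2.99-fold), chromosome 7 137438001 to 137439000 (3.03-fold) and chromosome 14 101988001 to 101989000 (5.30-fold, from 16 to 106 reads over the 6 pools) rose with all 6 exposed pools above every control pool, and chromosome 16 64899001 to 64900000 rose 2.30-fold with 5 of 6 above. The window on chromosome 14 was itself called in F1 (log2 fold change 1.50), near but apart from the region at 101991001 to 101994000 that rose there.

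The smallest p in F2 belonged to a window that fell, at chromosome 16 72208001 to 72209000, from 4.83 ± 0.838 to 1.99 ± 0.814 CPM (SD, n = 6; 0.428-fold; log2 fold change −1.22 ± 0.17, SE; edgeR adjusted p = 0.000188). Chromosome 1 159567001 to 159568000 (0.464-fold) and chromosome 13 30579001 to 30580000 (0.400-fold) fell with all 6 exposed pools below every control pool. Chromosome 10 20890001 to 20891000 (0.286-fold) and chromosome 11 82209001 to 82210000 (0.189-fold) fell with 5 of 6 below. Control F3 differed from control F2, which both comparisons use, at some of these windows, with 1.64 ± 0.899 CPM at chromosome X 136411001 (log2 fold change over control F2 1.42; edgeR adjusted p = 0.0116) and 1.69 ± 0.745 at chromosome 1 159567001 (−1.04; edgeR adjusted p = 0.0116). Of the 50 calls, control F3 lay on the exposed side of control F2 in 96 percent and control F1 in 94 percent. The median shifts were 0.81 and 0.36 (log2), against 1.30 in exposed F2, and the shared control F2 pools contribute to them. The F2 count was 2 against control F3, 2 with limma-trend and 1782 with edgeR's exact test. TMM within classes of read count gave 48 higher and 26 lower. Without single pools it ran from 12 (without exposed F2 replicate 5) to 259 (without exposed F2 replicate 1).

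F3 males were carried by a mother given DDT, with vinclozolin and JP8 in the earlier pregnancies of the lineage. Exposed F3 sperm differed from control F3 sperm in 3 of 1261359 windows. At chromosome 3 23694001 to 23695000 reads nearly vanished, from 1.52 ± 0.738 to 0.130 ± 0.201 CPM (SD, n = 6; 193 against 17 reads; 0.0963-fold; log2 fold change −3.38 ± 0.37, SE; edgeR adjusted p = 5.43e-10). The call held in all 8 settings of scaling, covariates, filter and test under which the window was tested (adjusted p 1.72e-14 to 1.38e-05). Chromosome 1 71474001 to 71475000 fell 0.342-fold, from 1.45 ± 0.634 to 0.488 ± 0.223. Chromosome 3 27129001 to 27130000 rose 3.95-fold, from 0.240 ± 0.138 to 0.927 ± 0.396 CPM (SD, n = 6; edgeR adjusted p = 0.0285 for both). These 2 calls held less well, in 5 of 9 and 6 of 8 settings and each in 6 of 12 fits without 1 pool. Windows at chromosome 1 53416001 to 53417000 (5.13-fold), chromosome 18 55812001 to 55813000 (4.59-fold) and chromosome 15 13890001 to 13891000 (0.304-fold) did not pass the test (edgeR adjusted p 0.0655 to 0.0872), although all 6 exposed pools lay beyond every control pool at each.

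At chromosome 3 23694001 the other control groups measured 0.529 ± 0.466 CPM in control F1 and 1.02 ± 0.914 in control F2 (SD, n = 6). The other exposed groups measured 1.07 ± 0.333 in F1, 0.816 ± 0.674 in F2, 0.716 ± 0.465 in F4 and 0.650 ± 0.293 in F5 (SD, n = 6). The near loss in exposed F3 was thus not seen in exposed F4 and F5. The number of F3 calls rested on the control group: exposed F3 differed from control F1 in 4506 windows and from control F2 in 5842. Without control F3 replicate 5 the comparison with control F3 called 182, and edgeR's exact test called 89 with all pools.

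F4 males came from an untreated pregnancy and were compared with control F3, so exposure is not separated there from 1 generation or from any batch. Reads were higher in 7 windows and lower in 2 of 1300898. At chromosome 19 50419001 to 50420000 they rose 2.68-fold, from 0.755 ± 0.916 to 2.36 ± 0.588 CPM (SD, n = 6; log2 fold change 1.42 ± 0.24, SE; edgeR adjusted p = 0.00798). Chromosome 2 237887001 to 237888000 (1.84-fold), chromosome 9 103427001 to 103428000 (2.12-fold) and chromosome 3 36093001 to 36094000 (2.00-fold) rose with 4, 2 and 3 of 6 exposed pools above every control pool (edgeR adjusted p = 0.0329 for each). A window with few reads, chromosome 8 113764001 to 113765000, went from 5 reads over the 6 control pools to 55 over the 6 exposed pools.

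The 2 windows that fell in exposed F4 were chromosome 3 51360001 to 51361000, from 0.733 ± 0.315 to 0.0881 ± 0.106 CPM (SD, n = 6; 0.145-fold; edgeR adjusted p = 0.00180), and chromosome 1 71474001 to 71475000, which had fallen in F3 too (0.356-fold; edgeR adjusted p = 0.0206). Chromosome 7 123397001 to 123398000 did not pass the test at 0.621-fold (edgeR adjusted p = 0.109). Control F3 replicate 5 stood apart from its group at chromosome 2 237887001 (4.25 CPM against at most 2.23 in the other 5) and chromosome 9 103427001 (2.78 against at most 1.10). Without it 123 windows were called, without exposed F4 replicate 3 10, and without any other single pool 1 to 3. Limma-trend called 2, and all 8 groups in 1 fit called 0 (edgeR; 84034 at an unadjusted p under 0.05). Against control F1 and control F2, exposed F4 differed in 4970 and 2814 windows.

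F5 males came from a second untreated pregnancy. They were compared with control F3, so exposure is not separated there from 2 generations or from any batch. Their sperm carried more reads in 13 windows and fewer in 23 of 1315252. The window at chromosome 1 71474001 to 71475000 fell to 0.175-fold, from 1.45 ± 0.634 to 0.253 ± 0.100 CPM (SD, n = 6), with all 6 exposed pools below every control pool (log2 fold change −2.51 ± 0.29, SE; edgeR adjusted p = 4.15e-09). Chromosome 3 51360001 to 51361000 fell 0.149-fold, chromosome 3 124845001 to 124846000 0.546-fold and chromosome 9 104711001 to 104712000 0.372-fold, each with all 6 exposed pools below every control pool. At chromosome 11 54522001 to 54523000 (0.467-fold) no exposed pool lay below every control pool, because control F3 replicate 4 measured 0.817 CPM and the other 5 control pools 2.97 to 4.18.

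Chromosome 13 45351001 to 45352000 rose 2.48-fold in exposed F5, from 0.855 ± 0.185 to 2.20 ± 0.392 CPM (SD, n = 6; log2 fold change 1.31 ± 0.20, SE; edgeR adjusted p = 0.000208), with all 6 exposed pools above every control pool. The same separation held at chromosome X 36443001 to 36444000 (1.95-fold) and chromosome 4 176741001 to 176742000 (2.86-fold), while chromosome 10 58296001 to 58297000 (2.19-fold) had 5 of 6 and chromosome 2 115810001 to 115811000 (4.21-fold) 2 of 6 pools above every control pool. Limma-trend called 4 windows and edgeR's exact test 133. Without single pools the count ran from 13 (without exposed F5 replicate 4) to 88 (without control F3 replicate 5). At chromosome X 36443001 control F1 measured 2.16 ± 0.149 CPM and control F2 2.57 ± 0.471, between control F3 (1.57 ± 0.580) and exposed F5 (3.02 ± 0.448; SD, n = 6). Of the 36 calls, control F1 lay on the exposed side of control F3 in 97.2 percent and control F2 in 91.7 (median log2 0.52 and 0.64, against 1.16 in exposed F5), to which the shared control F3 pools contribute.

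**Figure D2:**
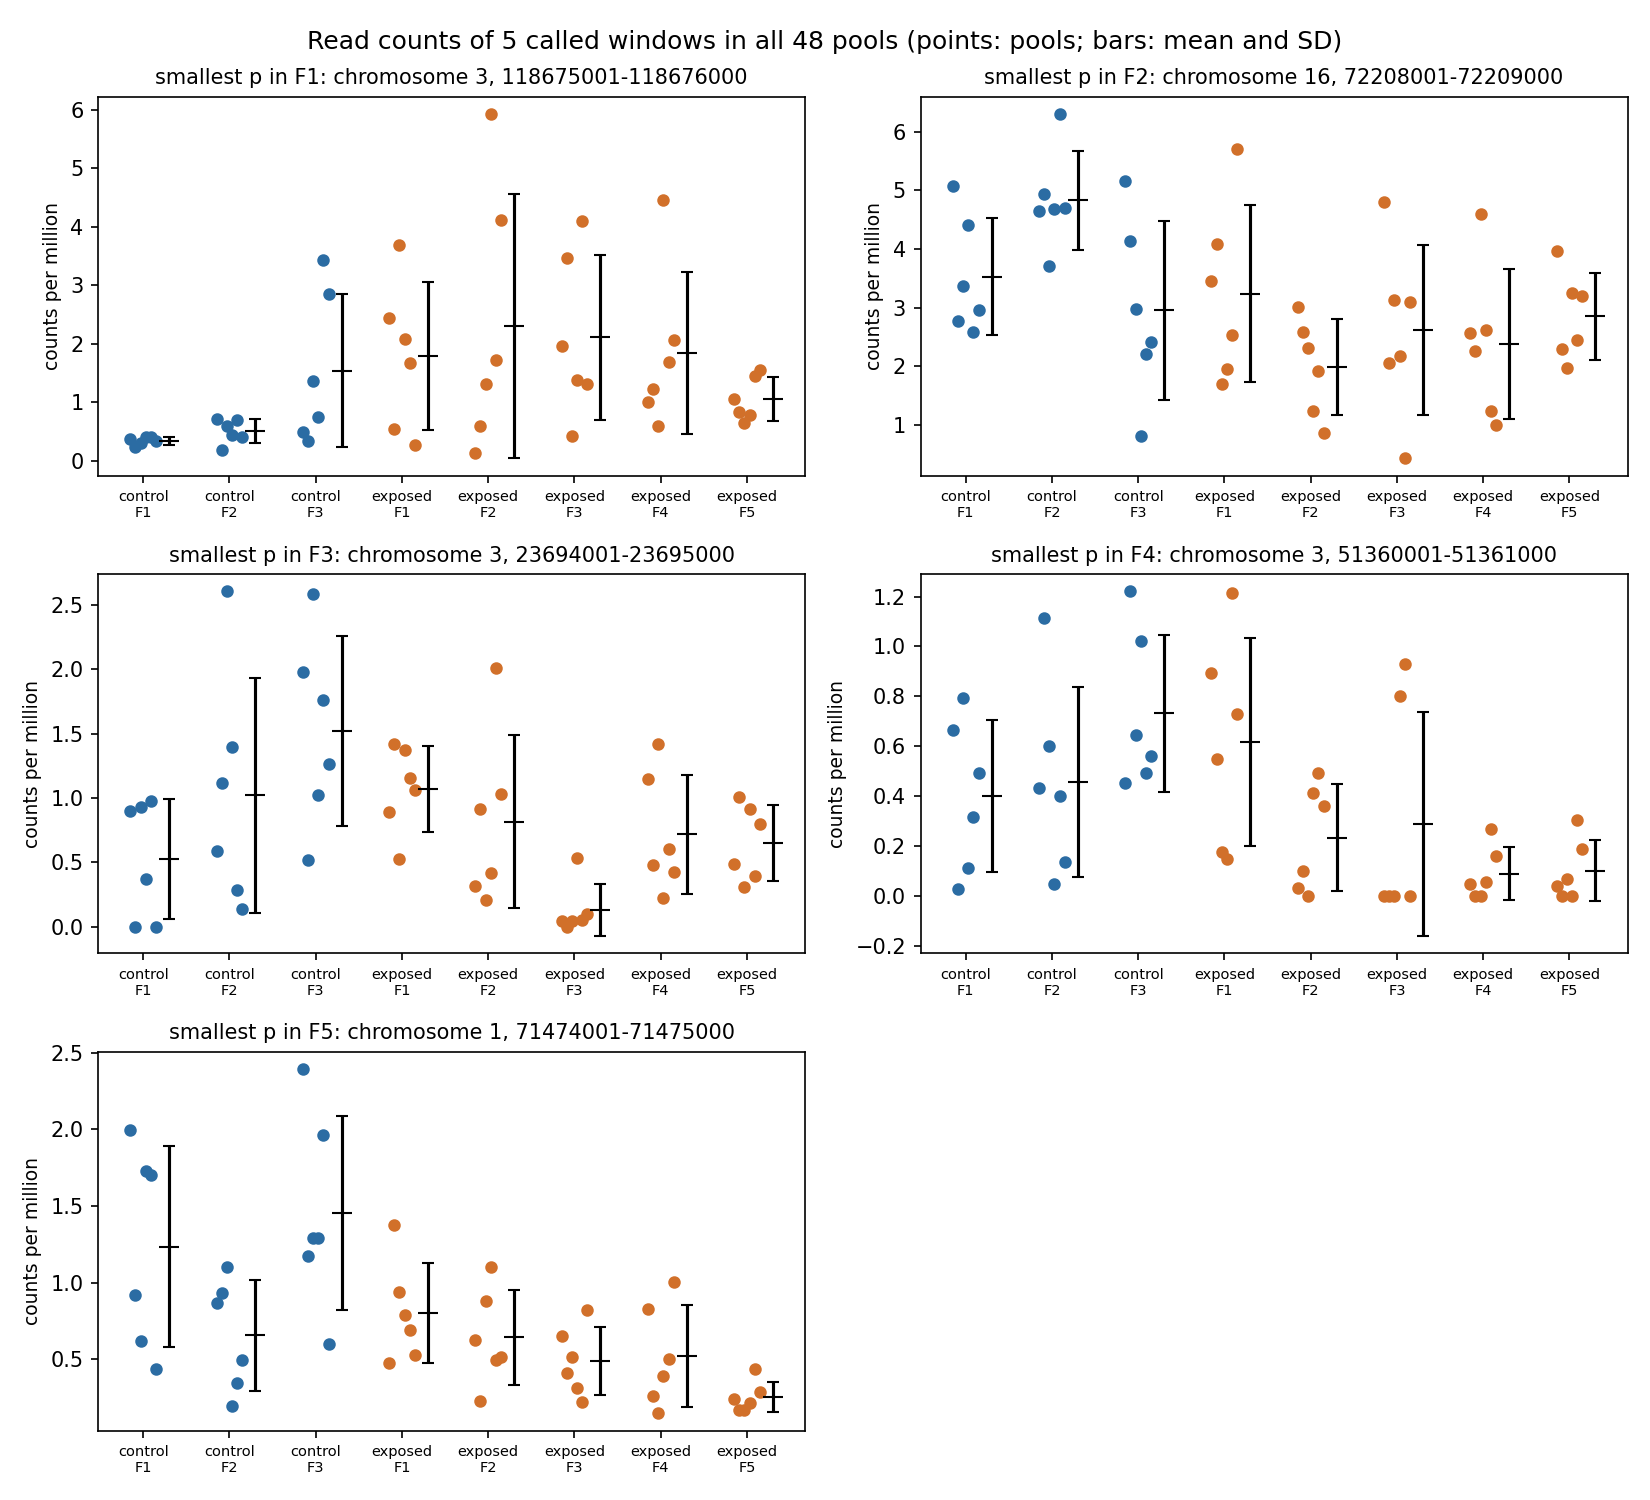
Reads (CPM) in each of the 48 pools (points) at the window with the smallest p in each main comparison, by group, with bars for mean and SD (n = 6). At chromosome 1 71474001 the mean falls from 1.45 in control F3 to 0.488, 0.522 and 0.253 in exposed F3, F4 and F5, and control F2 lies at 0.656.

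Control groups of different generations were compared to show differences that arise without exposure, where generation is not separated from any batch of collection or sequencing. Control F3 sperm carried more reads than control F1 sperm in 1510 windows and fewer in 252, control F2 more than control F1 in 80 and fewer in 17, and control F3 and control F2 differed in 8. The windows named for these comparisons were chosen by smallest p after their values were seen. Chromosome 3 118675001 to 118676000, the leading window of F1, also led control F3 against control F1 (log2 fold change 2.27 ± 0.29, SE; edgeR adjusted p = 1.87e-06). The F1 region on chromosome X, 73399001 to 73402000, rose there too, from 3.47 ± 0.827 to 5.66 ± 1.50 CPM per window (SD, n = 6). A region of 4 windows at chromosome 10 70352001 to 70356000 also rose, from 6.88 ± 1.04 to 10.4 ± 3.89. Adjoining windows at chromosome 1 80355001 and 80356001 rose from control F1 to control F2 (log2 fold change 1.12 for each), and the second fell from control F2 to control F3 (−1.03). The count of control F3 against control F1 ran from 32 (without control F3 replicate 6) to 4313 (without control F3 replicate 1). That of control F2 against control F1 ran from 1 (without control F2 replicate 5) to 872 (without control F1 replicate 6).

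**Figure D3:**
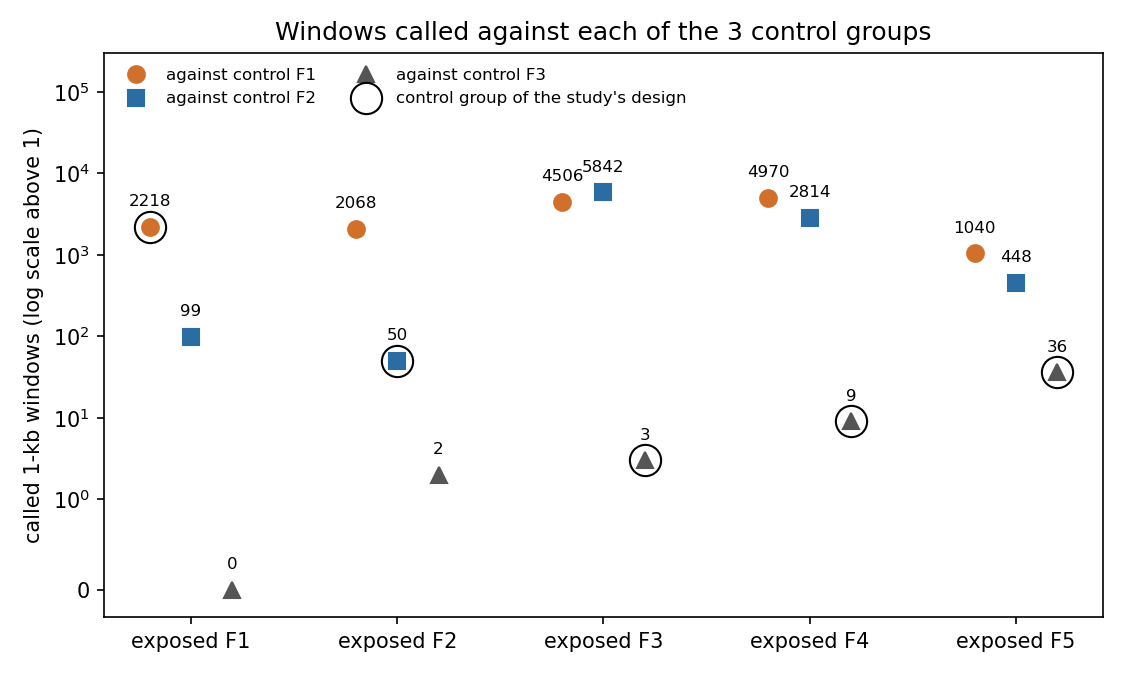
Number of called windows (log scale above 1) for each exposed generation against control F1, control F2 and control F3, with a ring around the control group of the study's design. Exposed F1 differs from control F1 in 2218 windows and from control F3 in 0; exposed F3 differs from control F1 in 4506, from control F2 in 5842 and from control F3 in 3.

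Comparisons within the exposed lineage did not use any control pool. Generation, distance from the treated pregnancies and any batch are not separated in them. Exposed F5 sperm differed from exposed F3 sperm in 58 windows, 25 higher and 33 lower. Chromosome 20 19484001 to 19485000 rose from 2.29 ± 0.561 to 4.76 ± 1.10 CPM and chromosome 5 6373001 to 6374000 from 2.14 ± 0.699 to 4.48 ± 0.667 (SD, n = 6; edgeR adjusted p = 1.35e-05 for both; chosen after their values were seen). Among the windows that fell, 6 formed 1 region at chromosome 6 10806001 to 10814000 (mean log2 fold change −0.69), with 9.52 ± 3.54 CPM per window in exposed F3 and 5.91 ± 0.476 in exposed F5. Exposed F5 and exposed F4 differed only at chromosome 16 11451001 to 11452000 (log2 fold change 0.81; edgeR adjusted p = 0.0460), a call that ended with TMM within classes of read count. Between exposed F4 and exposed F3 edgeR called 0 windows, with 65812 of 1290358 at an unadjusted p under 0.05. The F5 against F3 count ran from 6 (without exposed F3 replicate 5) to 529 (without exposed F3 replicate 3). TMM within classes of read count gave 19 higher and 58 lower.

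Whether an effect differed between generations was tested directly for F1, F2 and F3. The test called 9 of 1300463 windows for F2 against F1, 28 with TMM within classes of read count, and 0 at an adjusted p under 0.01 (edgeR; 123813 at an unadjusted p under 0.05). Differences from F1 rest on the control F1 pools too, and generation is not separated in them from any batch. Reads at chromosome 10 20890001 to 20891000 fell in F2, from 1.09 ± 0.254 to 0.336 ± 0.210 CPM, and stood at 0.711 ± 0.126 in control F1 and 0.865 ± 0.227 in exposed F1 (SD, n = 6; difference of log2 fold changes −2.17 ± 0.37, SE; edgeR adjusted p = 0.0135). Chromosome 10 47162001 to 47163000, which had fallen in F1, did not fall in F2 (2.08 ± 0.36, SE; edgeR adjusted p = 0.0142). It measured 1.23 ± 0.401 CPM in control F1, 0.673 ± 0.292 in control F2, 0.473 ± 0.0939 in exposed F1 and 1.18 ± 0.293 in exposed F2 (SD, n = 6). For F3 against F1 it called 5 windows (4 with TMM within classes, 1 at an adjusted p under 0.01), led by chromosome 3 23694001 to 23695000 (−4.38 ± 0.59, SE; edgeR adjusted p = 1.45e-05). No window passed for F3 against F2 with edgeR (75481 at an unadjusted p under 0.05).

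A few windows were called in the same direction in more than 1 generation. F1 and F2 shared 9, of which 6 rose and 3 fell, against 0.0425 for independent lists of the same sizes; the windows that rose in F1 are not independent, with a mean pairwise correlation of 0.631 within the other groups. They included chromosome 3 118675001 (log2 fold changes 2.48 and 2.02), chromosome 14 101988001 (1.50 and 2.41), chromosome 13 30579001 (−1.16 and −1.32) and chromosome X 136411001 (0.96 and 1.64). At these 4 control F3 measured 1.54, 0.565, 1.06 and 1.64 CPM, toward the exposed groups from control F1 (0.344, 0.312, 1.99 and 0.788) and control F2 (0.503, 0.116, 2.14 and 0.641). F1 and F4 shared 3 windows that rose, among them chromosome X 43088001 to 43089000 (1.32 and 1.23), F1 and F5 shared 1, and no window was shared by F1 and F3 or by F2 and a later generation. Over all F1 calls tested there, the sign was the same in 78.5 percent in F2, 53.7 in F3, 53.1 in F4 and 27.1 in F5. The last 3 use control F3, whose own level enters these shares. Shifts were also averaged over 1000 windows chosen with pools 1 to 3, each window signed by its direction in exposed F1. Control F3 lay 0.42 ± 0.39 (log2, SD, n = 6) from the other control F1 pools in that direction, and the other exposed F1 pools 0.38 ± 0.28 (SD, n = 3). With pools 4 to 6 the shifts were 0.39 ± 0.23 and 0.49 ± 0.22. Exposed F3, F4 and F5 were shifted in that direction by 0.53, 0.54 and 0.32 in the first set and 0.47, 0.48 and 0.35 in the second. One window, chromosome 1 71474001 to 71475000, was called in F3, F4 and F5, with log2 fold changes of −1.55, −1.49 and −2.51. F4 and F5 also shared chromosome 3 51360001 (−2.78 and −2.75) and chromosome 4 176741001 (1.52 and 1.51), and F3 and F5 shared chromosome 3 23694001 (−3.38 and −1.27). At chromosome 4 176741001 control F3 stood at 0.370 ± 0.134 CPM, below control F1 (0.771 ± 0.135) and control F2 (0.919 ± 0.148), with 1.07 in exposed F4 and F5. At chromosome 3 51360001 it stood at 0.733 ± 0.315, with control F1 at 0.401 ± 0.304 and control F2 at 0.455 ± 0.381 (SD, n = 6). At chromosome 3 23694001 it stood at 1.52 ± 0.738, with control F1 at 0.529 ± 0.466, control F2 at 1.02 ± 0.914 and exposed F5 at 0.650 ± 0.293 (SD, n = 6).

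F3, F4 and F5 share the control F3 pools, which by itself makes their fold changes alike. Across 223597 windows, which are not independent replicates, the correlation of fold changes was 0.549 for F3 and F4 (covariance 0.0264), 0.373 for F3 and F5 (0.0190) and 0.536 for F4 and F5 (0.0245). Simulated unchanged groups that shared the same simulated controls gave 0.497 (0.0203), 0.507 (0.0204) and 0.512 (0.0204). With 3 control pools for 1 generation and the other 3 for the other, correlations lay between −0.161 and 0.137, and at most 2 windows were shared. At an unadjusted p under 0.001, F3 and F4, F3 and F5, and F4 and F5 shared 46, 23 and 58 windows with a mean of at least 20 reads, against 7, 16 and 14 in the simulation. The simulation drew the windows independently of each other, whereas windows in the data can move together. The excess over it therefore does not show sharing beyond the common controls. At chromosome 1 71474001 control F2 measured 0.656 ± 0.363 CPM (SD, n = 6), nearer to the exposed groups than to control F3, and control F1 1.23 ± 0.655, nearer to control F3.

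Called windows were spread over the chromosomes with few exceptions. Chromosome 14 held 97 of the 1613 windows that rose in F1, 6.01 percent against 4.08 percent of tested windows (odds ratio 1.50; Fisher's exact test, adjusted p = 0.0108). Chromosome X held 64 of them, 3.97 against 2.58 percent (odds ratio 1.56; Fisher's exact test, adjusted p = 0.0203). In F2, 5 of the 27 windows that fell lay on chromosome X (18.5 against 2.55 percent; odds ratio 8.69; Fisher's exact test, adjusted p = 0.0239). Both results for chromosome X missed the threshold with TMM within classes of read count (odds ratios 1.13 and 6.95) and at an adjusted p under 0.01 (2.07 and 7.65). The 5 windows in F2 fell to 0 without control F2 replicate 4, exposed F2 replicate 3 or exposed F2 replicate 5, and with limma-trend. In these settings the number of all F2 calls fell as well.

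The share of all reads that fell on chromosome X was lower in exposed F2 than in control F2, at 2.83 ± 0.0232 against 2.96 ± 0.0743 percent (SD, n = 6; exact two-sided permutation p = 0.00216, adjusted p = 0.0325), with all 6 exposed pools below every control pool. It was lower in exposed F3 than in control F3 as well, at 2.79 ± 0.0708 against 2.94 ± 0.0784 percent (SD, n = 6; exact permutation p = 0.00866, adjusted p = 0.0433; 4 of 6 below every control pool). In F1 (2.90 and 2.90 percent), F4 (2.86 and 2.94) and F5 (2.92 and 2.94) the shares did not differ by the exact permutation test (adjusted p 0.162 to 0.931). Chromosome Y held 0.106 ± 0.00179 percent of reads in exposed F2 and 0.109 ± 0.00141 in control F2 (SD, n = 6; exact permutation p = 0.00866, adjusted p = 0.0433; 4 of 6 below every control pool). Its lower share in exposed F3 failed the correction (exact permutation p = 0.0325, adjusted p = 0.122). The 1 percent of windows with the most reads held 10.0 to 11.1 percent of reads per group, with no difference past the exact permutation test in any main comparison (adjusted p 0.172 to 0.724).

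**Figure D4:**
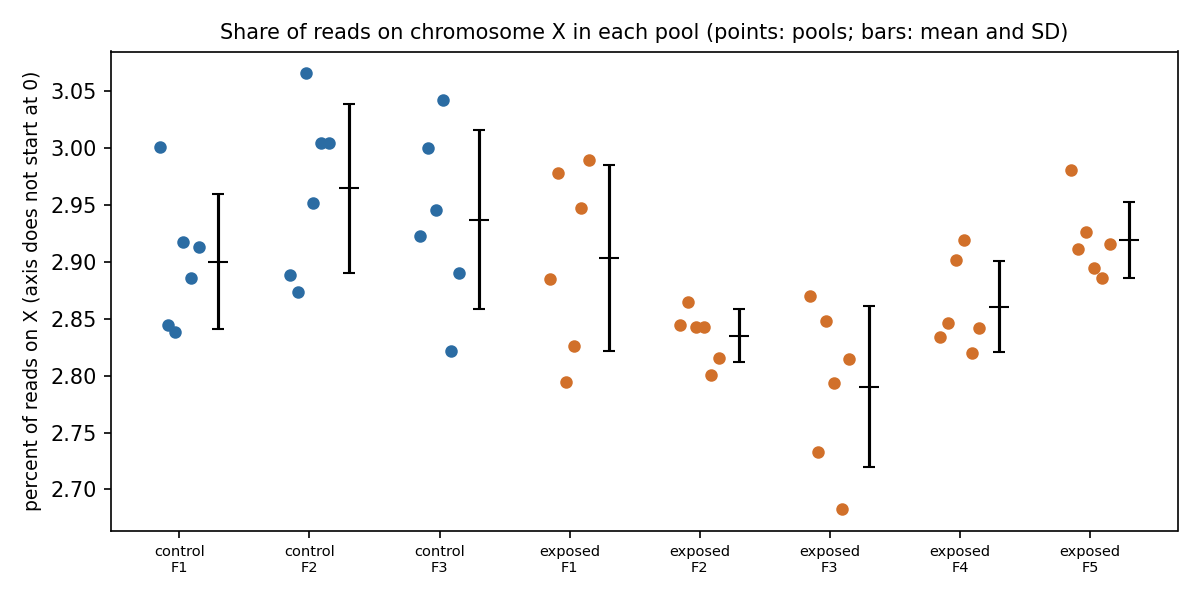
Percent of reads on chromosome X in each pool (points), by group, with bars for mean and SD (n = 6); the vertical axis does not start at 0. Exposed F2 (2.83) and exposed F3 (2.79) lie lowest, below control F2 (2.96) and control F3 (2.94).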

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

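For the number of F1 calls, the tests of the control groups and of read abundance were chosen after the counts had been seen, as was the test of the first component for the chromosome X share; the tests of depth, of the Y share, of windows that move together and of other splits of 2 groups were written down before their results. The criterion for the control groups was also reworded after its own result had been seen. Taken on the mean of control F2 and control F3 it would have been met, while the stricter form used, on each of them, left the question open. For differences of effects the number of splits was lowered to 32 after results from 40 had been seen.

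In windows that separate the F1 groups, the other groups were shifted from held-out control F1 pools toward exposed F1, which may raise the F1 count. In the 1000 windows that best separated pools 1 to 3 of the F1 groups, values were signed by the direction of the F1 change. Pools 4 to 6 of exposed F1 lay 0.38 ± 0.28 (log2, SD, n = 3) from those of control F1 in that direction, control F3 0.42 ± 0.39 and control F2 0.16 ± 0.13 (SD, n = 6). With the pools exchanged the values were 0.49 ± 0.22, 0.39 ± 0.23 and 0.18 ± 0.10, so that control F2 covered as little as 36.3 percent of the distance. A deviation of the control F1 pools from all other groups cannot be told apart from an effect of the vinclozolin pregnancy. The mean of control F3 leans to the former and control F2 leaves part to the latter. The control F3 pools were uneven, which weakens their weight here. In windows called higher in F1, pools 1, 2 and 4 lay at −0.39 to −0.33 from their group mean (log2), and pools 3, 5 and 6 at 0.15 to 0.57. The tables argue against an abundance trend between libraries as the whole cause, since taking it out by classes of read count raised the F1 count to 4454. Depth stays open, as the signed level of these windows followed log2 depth within the 6 other groups with r = −0.37 (permutation p = 0.0528, rho −0.35), a sign that fits the lower depth of exposed F1.

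A lower share of reads on chromosome X marked exposed F2 and exposed F3. Fewer X-bearing sperm would raise the Y share, but that share was also lower in exposed F2 (difference −0.0033 percentage points, exact permutation p = 0.00866). This speaks against it unless a component of the whole library lowers both shares, and the Y share was not adjusted for one. Over all pools, the first principal component of the autosomal windows followed the X share (r = −0.614, rho −0.646 over 48 pools; −0.512 within groups, permutation p = 0.00026; r = −0.596 without the 2 farthest pools). In the 18 control pools alone it did not pass the test (r = −0.345, permutation p = 0.164, rho −0.156; r = −0.0391 without the 2 farthest pools), so that its link to the X share apart from exposure is uncertain. After its slope was taken out, the F2 difference kept 55.1 percent of its size with an exact permutation p of 0.0844 and the F3 difference 86.1 percent with p = 0.00649, so such a component may account for part of F2 and cannot be told apart there from an effect of exposure.

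The windows called higher in exposed F1 rose and fell together in pools that had no part in choosing them. Over the 36 pools of the other 6 groups, the mean pairwise correlation of 1321 of these windows within groups was 0.631. In 200 random sets, matched on read count and drawn from windows far from a call in F1, it was at most 0.0664. Taking out the first 3 components of such matched windows left 0.179, above the 0.0106 of the random sets, although most of the correlation went with them. Those 3 components are therefore not the whole cause. Components and random sets both came from windows far from an F1 call, so a library component that such windows carry weakly stays possible. Depth stays open (r = −0.326 within groups, permutation p = 0.0992, rho −0.309). No biological explanation was tested, and differences between the animals of a pool, such as litter or inherited sequence variants, stay possible but untested.

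Other splits of the same pools, the real one among them, were fitted on windows with a mean of at least 15 reads. Of 40 splits only the real one, 1, reached its own count for F1 (6409, highest other 1102), F2 (24, highest other 1), control F3 against control F1 (4833, highest other 1243) and exposed F5 against exposed F3 (172, highest other 128). Of 32 splits only the real one, 1, did for the F2 effect minus the F1 effect (160, highest other 1). A share of 1 in 40 or 1 in 32 is the smallest these splits can give. It was not corrected over the comparisons, so it makes chance less likely as the source of these counts without excluding it. For exposed F5 against exposed F3 the margin was narrow, and leaving out 1 pool moved its count from 6 to 529. Other splits reached the real count, and chance stays fully open, for F3 (1 call; 8 of 40 splits had as many, highest 3143), F4 (7; 4 of 40, highest 24), F5 (62; 2 of 40, highest 295), control F2 against control F1 (154; 2 of 40, highest 1673), control F3 against control F2 (8; 4 of 40, highest 576), exposed F5 against F4 (1; 14 of 40, highest 8) and the F3 effect minus the F1 effect (6; 2 of 32, highest 7). For exposed F4 against F3 and the F3 effect minus the F2 effect the real count was 0 (edgeR; 65812 and 75481 at an unadjusted p under 0.05 in the comparison over all tested windows), which every split reaches, so the splits test nothing there. The split with 3143 calls set control F3 pools 1, 2 and 4 with exposed F3 pools 3, 4 and 6 against the rest, and the one with 1673 set control F1 pools 1 to 5 with control F2 pool 1 against the rest. Counts several times the real one may reflect a structure of the samples that the labels do not name. In the split with 3143 calls, the first principal component of the autosomal windows ran from −0.115 to 0.0689 on the side named and from 0.0556 to 0.358 on the other. In the split with 1673 calls it ran from −0.163 to −0.106 and from −0.144 to −0.0633. These values were seen after the splits, and whether the component raised the counts was not tested. The second of these splits differs from the labels only by an exchange of 1 pool.

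Single pools lay far from the other 5 of their group in 2 of 32 groups of pool measures (1.6 expected) and 10 of 85 groups at named windows (4.25 expected); chance alone marks about 1 in 20. The Y share was 0.106 percent in control F3 replicate 6 (0.110 to 0.112 in the others) and 0.115 in exposed F5 replicate 1 (0.110 to 0.112). CPM stood apart at chromosome 2 29456001 in control F1 replicate 1 (0.380), chromosome 11 82209001 in control F2 replicate 2 (1.56), chromosome 1 53416001 in exposed F3 replicate 5 (1.26), chromosome 18 55812001 in exposed F3 replicate 2 (1.12) and chromosome 3 23694001 in exposed F3 replicate 4 (0.535). They also did at chromosome 2 237887001 and chromosome 9 103427001 in control F3 replicate 5 (4.25 and 2.78), chromosome 2 115810001 and chromosome 11 54522001 in control F3 replicate 4 (1.02 and 0.817) and chromosome 4 176741001 in exposed F5 replicate 6 (1.88).

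Whether effects differed between generations was tested with edgeR on the difference itself, in log2 units; the windows given are those with the smallest p, chosen after their values were seen. These differences rest on the control F1 pools too, generation is not separated from any batch, and chance is not excluded for the number of F3 minus F1 calls. At an adjusted p under 0.01, F2 minus F1 kept 0 windows (edgeR; 123813 at an unadjusted p under 0.05) and F3 minus F1 1. The F2 effect minus the F1 effect was 2.17 at chromosome 3 152763001, −2.17 at chromosome 10 20890001, 2.08 at chromosome 10 47162001, 1.82 at chromosome 20 4495001 and 1.40 at chromosome 1 80990001. The F3 effect minus the F1 effect was −4.38 at chromosome 3 23694001, 2.40 at chromosome 10 70023001, 2.63 at chromosome 3 133270001, −1.79 at chromosome 4 100724001 and 2.17 at chromosome 18 59052001.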

How the results depend on the processing

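Scaling within classes of read count, surrogate variables, other control groups, leaving out the least correlated pools and the top 5 percent of windows were chosen after seeing the data; the other alternatives were planned. Counts below are in the order F1, F2, F3, F4, F5 unless named, and the cause of a change was not tested unless given.

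DESeq2 size factors (2375, 51, 3, 9, 39) and total count scaling (2634, 59, 3, 9, 36) left all 5 counts within 1.5 times the values reported, 2218, 50, 3, 9 and 36. The exact test called 3960, 1782, 89, 21 and 133, and limma-trend 113, 2, 1, 2 and 4. No filter gave 1453, 147, 15, 13 and 47. A mean of at least 20 reads, with fewer windows tested, gave 7525, 9, 0, 0 and 51 (edgeR; 13038 in F3 and 11775 in F4 at an unadjusted p under 0.05). All 8 groups in 1 fit gave 489, 77, 1, 0 (84034 at an unadjusted p under 0.05) and 6. An adjusted p under 0.01 left 422, 10, 1, 2 and 15, and an unadjusted p under 1e-06 242, 33, 9, 11 and 34. Classes of read count gave 4454, 74, 3, 11 and 45, 2 surrogate variables 5851, 396, 4, 11 and 51, and leaving out the least correlated pools 2979, 28, 3, 5 and 24.

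Exposed F1 against control F2, control F3 and all 18 controls gave 99, 0 (58922 at an unadjusted p under 0.05) and 21; exposed F2 against control F1, control F3 and all 18 gave 2068, 2 and 16. Against control F1, control F2 and all 18, exposed F3 gave 4506, 5842 and 1745, exposed F4 4970, 2814 and 515, and exposed F5 1040, 448 and 89.

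Control F2 against F1, control F3 against F1 and control F3 against F2 gave 224, 5250 and 5 at a mean of at least 20 reads, 37, 3457 and 10 with classes of read count, 817, 2796 and 7 without the least correlated pools, and 4, 330 and 0 (80321 at an unadjusted p under 0.05) at an adjusted p under 0.01. Exposed F5 against F3 gave 170, 77, 5 and 12 in the same order; exposed F5 against F4 gave 0 with classes of read count (86931 at an unadjusted p under 0.05) and 0 at an adjusted p under 0.01 (edgeR; 88282). The F2 minus F1 difference gave 28 with classes and 0 at an adjusted p under 0.01 (edgeR; 123813 at an unadjusted p under 0.05), and F3 minus F1 gave 1.

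Without each pool in turn, replicates 1 to 6, F1 gave 1479, 598, 708, 1387, 676 and 2113 (control F1) and 1179, 3765, 838, 1260, 1341 and 3168 (exposed F1). F2 gave 30, 50, 16, 15, 16 and 14 (control F2) and 259, 72, 17, 45, 12 and 18 (exposed F2). F3 gave 1, 2, 1, 5, 182 and 7 (control F3) and 10, 2, 4, 1, 2 and 4 (exposed F3). F4 gave 1, 2, 1, 3, 123 and 3 (control F3) and 3, 2, 10, 3, 3 and 3 (exposed F4). F5 gave 65, 53, 27, 32, 88 and 25 (control F3) and 15, 36, 14, 13, 39 and 16 (exposed F5). Control F2 against F1 gave 8, 3, 2, 15, 26 and 872 (control F1) and 612, 199, 30, 2, 1 and 8 (control F2). Control F3 against F1 gave 1018, 493, 457, 995, 562 and 2001 (control F1) and 4313, 3242, 883, 2561, 541 and 32 (control F3). Control F3 against F2 gave 5, 4, 7, 0, 4 and 3 (control F2) and 12, 16, 5, 8, 1 and 5 (control F3). Exposed F4 against F3 gave 0 to 3, exposed F5 against F4 0 to 32, the highest without exposed F4 replicate 3, and exposed F5 against F3 48, 37, 529, 31, 6 and 247 (exposed F3) and 7, 28, 16, 44, 58 and 19 (exposed F5).

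F1 and F2 shared 2 windows at an unadjusted p under 1e-06; F1 and F5 shared 2 within 1000 bp and 0 at an unadjusted p under 1e-06. With divided controls F3 and F4 shared 0 in both ways, and with pools 4 to 6 for the first F3 and F5 shared 1 and F4 and F5 shared 0, from fewer pools. Odds ratios for chromosome X were 2.07 and 1.13 in F1 and 7.65 and 6.95 in F2 at an adjusted p under 0.01 and with classes of read count, past the threshold no longer. Without each pool in turn, shares in exposed minus control ran from −0.0996 to −0.0555 (X, F4), −0.0035 to −0.00234 (Y, F3) and 0.00119 to 0.00236 (Y, F5), and the share of the top 1 percent from −0.796 to −0.414 (F3) and −0.731 to −0.348 (F4), each past an exact permutation p of 0.05 in some fits only; for the top 5 percent F3 gave −1.45 (exact permutation p = 0.0433). The lower X and Y shares of F2 and the lower X share of F3 passed in 12 of 12.

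The 44 named results reversed in 0 settings. Over all calls, called or not in the alternative, the sign was opposite in 372 of 2218 in F1 against control F3, 12 against control F2, and 1 of 36 in F5 against control F1. All 44 kept their side of the threshold with DESeq2 size factors, total count, classes of read count and 2 surrogate variables; limma-trend ended 25 calls, the exact test 10, all 8 groups 13, a mean of at least 20 reads 7 of the 28 tested, and control F3 in place of control F1 or F2 19 of 20. Over 528 combinations of a named result and a left-out pool, 81 calls ended and 7 arose. At these depths and this spread between pools, which the simulation did not separate, 2-fold changes were recovered in 13.4 to 23.9 percent of cases.

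Not run, for want of a gene annotation and sequence of the build: promoters and their alternatives, gene lists, CpG density classes, enrichment by CpG and sperm purity. No paired analysis was possible because the labels number pools within groups and name no link between pools of different groups.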

Other observations

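Mitochondrial reads, which no comparison above used, came to 132 ± 47.6 CPM in control F1 and 138 ± 31.8 in exposed F1, 99.2 ± 67.0 and 51.2 ± 14.3 in F2, and 120 ± 48.4 in control F3 against 67.5 ± 19.7, 87.1 ± 44.9 and 129 ± 19.5 in exposed F3, F4 and F5 (SD, n = 6). The F3 difference had an exact permutation p of 0.039 and failed the correction over 5 comparisons (adjusted p = 0.195). In each comparison every exposed pool lay within the range of its control pools.

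The authors' deposited test called 5607, 1771, 57, 6 and 161 windows in F1 to F5 at an adjusted p under 0.05. Of the windows called here, 1850 of 2218, 46 of 50, 2 of 3, 1 of 9 and 24 of 36 were among them. The authors had not tested 176, 2, 0, 2 and 1 of the windows called here. Log2 fold changes, with the sign aligned, correlated at 0.997 to 0.999 over 642484 to 777525 windows, which are not independent replicates.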
